A study of Mus musculus with 6 samples.

How the data were processed

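RNA from heart muscle of 6-week-old C57BL/6 mice was measured by sequencing in 6 samples, 3 wild type (WT) and 3 NS-DADm. Per the labels' protocols, tissue was frozen in liquid nitrogen, RNA was extracted with Trizol and a Qiagen kit, and libraries were built from total RNA by the standard protocols of BGI. Each sample had a table of genes and a table of transcripts, and the authors deposited estimated (expected) counts and FPKM in each. Per the file headers, the expected count is the number of reads assigned to a gene or transcript, and it was whole for most genes but not for 10.8% to 11.6% of the genes of a sample. FPKM is that count scaled by feature length and by the library's mapped reads or fragments, as the authors computed it, per the file headers. The submitters' processing notes name HISAT, an aligner, with no version. The estimator, the genome build and the annotation release are not given in the sources used here. The gene tables listed only genes with an FPKM of at least 0.01, so a gene missing from a sample's table was taken as 0 in that sample. The length column of the deposited tables was used only to name transcript models.

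The 6 gene tables held 17892 genes in all, of which 14449 were listed in all 6 samples. Of their identifiers, 17852 matched a gene of the RefSeq table for the assembly GRCm38.p6, which was used only for gene order along chromosomes. Because the authors' build is not named, no coordinates are given. The 1 row without a gene symbol, which held at most 3.2e-04% of a sample's counts, was left out. No mitochondrially encoded protein gene was listed. Total expected counts were 10183792 to 11205221 in the WT samples and 12262523 to 12758311 in the NS-DADm samples. A count of 3, for a feature of 1 kilobase, corresponded to an FPKM of 0.235 to 0.295. No pair of samples was a duplicate: the chi-square of their counts per gene, which is about 1 for repeated sampling of the same library, ranged from 3.5 to 18.1.

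Expected counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR with its defaults, libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3). Fold changes are NS-DADm over WT, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes, with 0.05 as the threshold. A gene that passed is called changed. Standard errors were derived from the fold change and the test statistic. The same test was applied to transcripts. The biological coefficient of variation was 0.106. The labels give the groups the same replicate numbers but state no pairing, so the comparison had no replicate block.

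The gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. There were 55 lists of pathways, protein complexes and markers of cell types that a heart sample can hold, of which 1 served only as a check of sex-linked genes. The 48 lists with at least 5 tested members were tested with camera (limma 3.58.1), which asks whether a list's genes shift relative to the other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with a correlation estimated from the data and fry, which tests whether the members move one way on balance, were alternatives. The 6 remaining lists, with fewer tested members, were not tested. The rule for naming genes takes targeted genes, Ncor1 and Hdac3 among them, then the 12 largest rises and the 12 largest falls among called genes with groups that do not overlap and a mean FPKM of at least 1, leaving out gene models named Gm or Rik. It adds up to 4 members with the smallest p of each called list and of each list with at least 2 called members, and the 3 most abundant markers of a called cell type. Any other gene named was chosen after its values were seen.

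The tests were checked on simulated counts with 200 genes changed. Of the simulated genes changed 1.5-fold, 47.8% were called, against 87.9% at 2-fold and 92.4% at 4-fold, over 12980 genes. There were 17 false calls, 10.1% of calls, above the nominal level. For transcripts, the shares called over 16627 transcripts were 4.6%, 21.9% and 54%, with 0 false calls. With no gene changed, 0 of 50 random lists were called, but genes were simulated independently, so this does not check lists of correlated genes. Estimated correlations in the tested lists ran from -0.041 to 0.883.

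The alternatives were DESeq2 size factors, no low-count filter, a minimum mean FPKM of 1, a replicate block, leaving out each sample, DESeq2's Wald test (version 1.42.0), limma on log2(FPKM + 1) and on log2(FPKM + 0.1), a fold-change minimum and a looser threshold. Alternatives added after the data were seen were an atrial score as a covariate, thinning of all libraries to equal depth, fits within libraries of low or high atrial transcripts, and removal of the genes nearest to Ncor1. A test of called genes by position in the gene order, at 5 window widths, was also added then, as was a camera test of the Gene Ontology terms given in the deposited tables. Chromosomal shares were compared with Fisher's exact test (scipy 1.17.1, Python 3.11.15), two-sided. Intervals on ratios of low counts are exact Poisson intervals at 95% and cover counting error only.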

Results

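Gene expression was measured by RNA sequencing in the myocardium of 6-week-old C57BL/6 mice, in 3 wild type (WT) samples and 3 NS-DADm samples. NS-DADm mice carry knock-in mutations in deacetylase activating domains of nuclear receptor corepressors, NCOR (encoded by Ncor1) among them, through which these proteins switch on the histone deacetylase HDAC3. The comparison asked how the heart muscle transcriptome of NS-DADm mice differs from that of WT mice. Total expected counts were 10768308, 10183792 and 11205221 in WT 1, 2 and 3 and 12364323, 12758311 and 12262523 in NS-DADm 1, 2 and 3, so that all NS-DADm libraries were deeper. Values per gene are FPKM as deposited, as mean ± SD over the 3 samples of a group. The labels do not say that each sample came from a separate mouse, so p-values measure the spread between these samples. The correlation of log2 expression between samples, across genes, was 0.982 to 0.989 within groups and 0.972 to 0.985 between them. All 6 samples expressed Xist (15.11 to 20.56 FPKM), while the Y-linked Ddx3y had at most 3 counts in a sample.

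The RNA levels of Ncor1 and of Hdac3 did not differ detectably. Ncor1 (gene ID 20185) had an FPKM of 22.9 ± 1.2 in WT and 24.3 ± 1.0 in NS-DADm (log2 fold change 0.10, SE 0.06, adjusted p = 0.432, edgeR). Hdac3 (gene ID 15183) stood at 29.8 ± 2.0 and 29.8 ± 0.80 (log2 fold change 0.03, SE 0.07, adjusted p = 0.884). Since the knock-in changes the proteins and need not change the amount of RNA, these levels do not check the sample labels.

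Between NS-DADm and WT myocardium, 420 of 13130 tested genes changed, 235 upward and 185 downward. Among called genes with a mean FPKM of at least 1, the deepest falls were in Pttg1 and Cyfip2. Pttg1 (gene ID 30939), which encodes securin, fell from 140.4 ± 8.6 to 4.67 ± 1.1 FPKM. Cyfip2 (gene ID 76884), a component of the WAVE complex that regulates actin, fell from 43.5 ± 3.3 to 2.62 ± 0.30 FPKM. Ndrg4 fell 4.36-fold, and the potassium channel subunit Kcne1 fell 5.10-fold. Among the rises, Mmp9, a gelatinase of the extracellular matrix, rose 8.86-fold, the sarcomeric Z-disc gene Myot 3.22-fold, the actin gene Acta1, which is abundant in skeletal and fetal heart muscle, 2.90-fold, and Mthfd2, an enzyme of mitochondrial one-carbon metabolism, 2.92-fold. In all 420 genes the samples of the groups did not overlap, which selection by the test on these same samples makes nearly certain. It is therefore no further support for the calls. Of all tested genes, 23.4% had groups that did not overlap, against 10% by chance.

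The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2370 genes had an unadjusted p under 0.05. Of the called genes, 101 changed by a log2 fold change of at least 1, 57 upward and 44 downward. Leaving out WT 2, WT 1, NS-DADm 1 or NS-DADm 2 lowered the number of genes changed to 117, 149, 181 and 273. Of the 24 genes with the largest changes, 15 stayed called without each sample in turn, Pttg1, Cyfip2, Ndrg4, Kcne1, Mmp9 and Myot among them. Without WT 1, WT 2 or NS-DADm 1 each of Acta1, Mthfd2, Fcgr4, Lrrc52, Retnla, Adra1d, Tpm2 and Bex1 lost its call, and so did Acta1 without WT 3, Tpm2 without NS-DADm 3, Bex1 without NS-DADm 2 and Dcaf12l1 without WT 1. Their highest adjusted p in such fits ran from 0.0535 for Dcaf12l1 to 0.147 for Bex1. With a score of atrial transcripts as a covariate Acta1 and Bex1 were not called (adjusted p = 0.0731 and 0.077), and with limma on log2(FPKM + 1) or log2(FPKM + 0.1) neither were Acta1 and Tpm2 (up to 0.0753 and 0.0689), nor Tpm2 with DESeq2's test (0.0609).

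The further largest rises among them were in Serpina3h, Olfr1372-ps1, Wdfy1, Fcna, Fcgr4, Lrrc52, Tpm2 and Retnla. Serpina3h had 0, 2 and 2 counts in the WT samples and 218, 61 and 51 in the NS-DADm samples, a ratio of 72.1 (95% interval 27.9 to 266). Olfr1372-ps1 rose from 0.90 ± 0.23 to 7.84 ± 0.79 FPKM, Wdfy1 from 2.67 ± 0.25 to 9.67 ± 1.4, Fcna from 1.91 ± 0.67 to 6.80 ± 1.3 and Fcgr4, an Fc receptor of myeloid cells, from 0.92 ± 0.13 to 3.24 ± 1.3. Lrrc52 rose 3.43-fold, Tpm2 2.79-fold and Retnla 2.74-fold. The further largest falls among them included Hcn2, B3galt2, Bex1, Slc6a17, the adrenergic receptor Adra1d, Dcaf12l1 and Kcnip2. Hcn2 fell from 9.41 ± 0.83 to 2.76 ± 0.46 FPKM and Kcnip2 from 108.9 ± 14 to 43.7 ± 4.5. Serpina3h belongs to a family of closely related serine protease inhibitor genes and Olfr1372-ps1 is a pseudogene, so their counts depend on how reads shared between related genes were assigned.

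**Figure D1:**
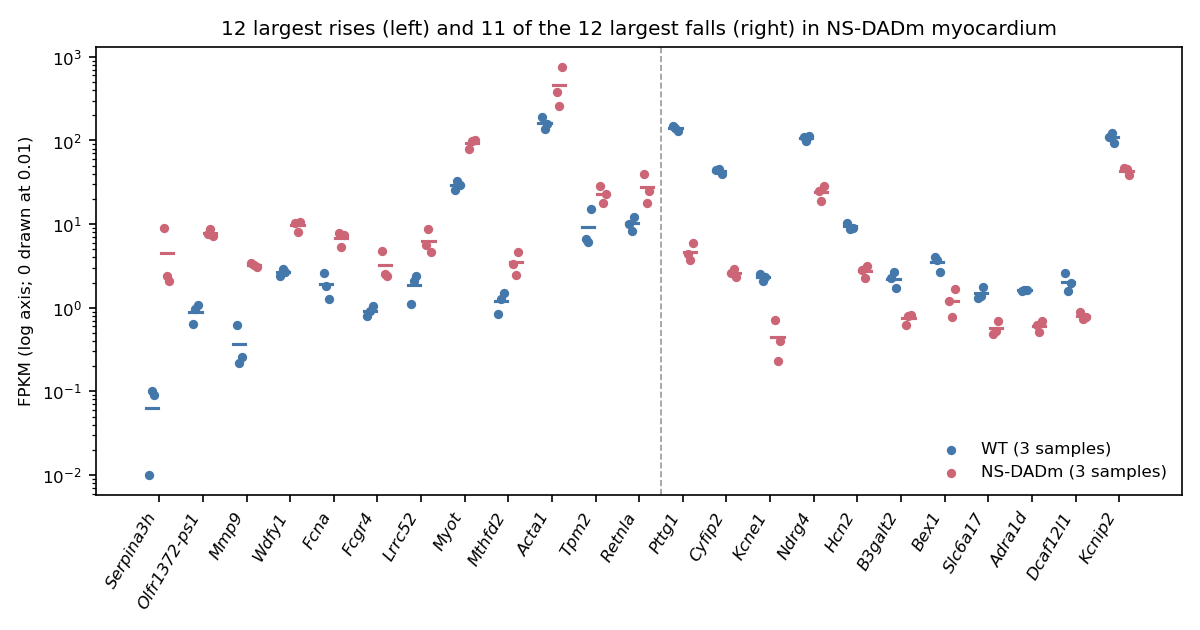
FPKM (log axis) of the 12 largest rises and 11 of the 12 largest falls in WT (blue) and NS-DADm (red) samples, with each sample as a point and the group mean as a bar. In every gene shown the 3 NS-DADm samples lie beyond the 3 WT samples, as the rule for naming genes required, and a sample at 0 is drawn at 0.01.

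Genes of the cardiac action potential were lower as a group. Of 31 tested genes of cardiac ion channels and gap junctions, 7 fell, 2 rose and 22 did not pass, and 12 fell and 2 rose when adjusted over the list alone. Beside Kcne1, Hcn2 and Kcnip2, the falls included the potassium channels Kcna4 (log2 fold change -2.25, SE 0.33) and Kcnd3 (-0.46, SE 0.08). Kcna4 was low in both groups, at 0.493 ± 0.006 FPKM in WT and 0.103 ± 0.035 in NS-DADm. Gja1, the main connexin of ventricular gap junctions, fell from 125.1 ± 14 to 88.7 ± 7.1 FPKM, and the calcium channel gene Cacna1g fell 1.84-fold. The sodium channel subunit Scn4b rose 1.69-fold and the potassium channel Kcnd2 1.45-fold. The list was called lower with camera (adjusted p = 0.000521, median log2 fold change -0.18) and by fry (adjusted p = 0.0314), but not with an estimated correlation (adjusted p = 0.25 with an estimated correlation). Kcnd3 lost its call without WT 2 or NS-DADm 1 (adjusted p up to 0.053), and with limma on log2(FPKM + 1) or log2(FPKM + 0.1) (up to 0.058). Gja1, Cacna1g, Scn4b and Kcnd2 were chosen after their values were seen.

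Immediate early genes, which respond within minutes to stimulation, were higher in NS-DADm. Of 23 tested, 9 rose and 14 did not pass, and 12 rose when adjusted over the list alone. Nr4a1 rose from 8.68 ± 1.0 to 23.1 ± 6.5 FPKM, Maff from 3.80 ± 0.59 to 8.05 ± 1.0, Ier5 from 12.9 ± 2.0 to 19.4 ± 0.37 and Junb from 8.16 ± 0.94 to 11.8 ± 0.86. The list was called with the preset correlation (adjusted p = 1.81e-11, median log2 fold change 0.43) and not otherwise (adjusted p = 0.328 with an estimated correlation). Ier5 lost its call without WT 2 or NS-DADm 1 (adjusted p up to 0.0699), and Junb without WT 1, WT 2, NS-DADm 1 or NS-DADm 2 (up to 0.111) and with the atrial covariate (0.0541).

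Lists of stress genes of heart muscle and of amino acid synthesis were also higher, though not in every member. Of 18 tested cardiac stress and fetal genes, 5 rose and 13 did not pass, and 7 rose and 1 fell when adjusted over the list alone. Ctgf, a matrix signalling protein, rose 2.25-fold, Acta1 2.90-fold, Fhl1 1.29-fold and Rcan1, a calcineurin regulator, 1.30-fold. Nppb (184.7 ± 48 FPKM in WT and 218.5 ± 28 in NS-DADm) and Myh7 (29.65 ± 5.2 and 49.1 ± 18) overlapped between the groups and were not called. Of 24 genes of the integrated stress response, which responds to amino acid shortage and mitochondrial stress, 5 rose and 7 did so when adjusted over the list alone. The transcription factors Atf5, Atf4 and Cebpb rose 1.62-fold, 1.32-fold and 1.59-fold. Both lists were called with camera (adjusted p = 0.000923 and 2.04e-05) and lost the call with an estimated correlation (adjusted p = 0.328 with an estimated correlation for each). Calls ended for Ctgf without WT 1 or WT 2 (adjusted p up to 0.0593), for Acta1 without WT 1, WT 2, WT 3 or NS-DADm 1 (up to 0.123), for Fhl1 without any sample but NS-DADm 2 (up to 0.109), and for Rcan1 without any 1 sample (up to 0.115). They also ended for Atf4 without WT 2, NS-DADm 1 or NS-DADm 2 (up to 0.0775), and for Cebpb without WT 1, WT 2, NS-DADm 2 or NS-DADm 3 (up to 0.109). Acta1 and Fhl1 were also not called with the atrial covariate (adjusted p = 0.0731 and 0.0587), nor were these genes, Rcan1 and Cebpb with limma on either log scale of FPKM (from 0.0523 for Rcan1 to 0.0795 for Fhl1).

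Macrophage and monocyte markers were higher as a group. All 19 tested markers had a positive fold change, 7 rose and 15 rose when adjusted over the list alone. The complement subunits C1qa, C1qb and C1qc rose 1.41-fold, 1.45-fold and 1.52-fold, and Folr2, a marker of resident macrophages, 1.66-fold. Lyz2, the most abundant, stood at 112.2 ± 15 and 137.6 ± 13 FPKM and did not pass (adjusted p = 0.119). The list was called with the preset correlation (adjusted p = 1.29e-11, median log2 fold change 0.44) and by fry (adjusted p = 0.00914), and missed the threshold with an estimated correlation (adjusted p = 0.0652 with an estimated correlation). C1qb lost its call without WT 2 (adjusted p = 0.0568), and Folr2 without WT 2 or NS-DADm 1 (up to 0.0927).

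Other inflammatory lists were higher with few members called. Of 26 inflammatory cytokine and acute-phase genes, 2 rose, 7 when adjusted over the list alone, with Ccl6 up 2.16-fold and Ccl9 1.82-fold, while Il1b, with 9 counts over the WT samples and 43 over the NS-DADm samples, did not pass (adjusted p = 0.0796). Of 40 interferon-stimulated genes, 37 had a positive fold change and 1 rose, Irf9, with 4 when adjusted over the list alone. Cd74 was the only one of 7 genes of MHC class II presentation that rose, 1.71-fold, with 5 when adjusted over the list alone, and H2-D1 was the only one of 15 class I genes, 1.41-fold, likewise when adjusted over the list alone. Adjusted p with an estimated correlation was 0.274, 0.407, 0.415 and 0.639 for these 4 lists, against 2.04e-05, 3.53e-06, 0.000221 and 0.00686 with the preset one. Irf9 and H2-D1 lost their calls without any sample but NS-DADm 2 (adjusted p up to 0.153 and 0.132), Cd74 without WT 1, WT 2 or WT 3 (up to 0.12), and the class I list without WT 3 or NS-DADm 1 (adjusted p = 0.0698 and 0.295). Cd74, H2-D1 and Irf9 were also not called with the atrial covariate (adjusted p = 0.0634, 0.0686 and 0.0982) or with limma on either log scale of FPKM (up to 0.0959, 0.0916 and 0.0772), nor was Cd74 with DESeq2's test (0.0697).

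Genes of the corepressor complex and of its nuclear receptor partners were called higher as lists, with median log2 fold changes of 0.24 and 0.11. Tbl1xr1, a subunit of the complex, rose from 6.80 ± 0.27 to 12.2 ± 0.76 FPKM (adjusted p = 0.000164) and was the only one of 7 members called, 3 when adjusted over the list alone. All 7 had a positive fold change (adjusted p = 0.000992 with camera, 0.0174 with fry, and adjusted p = 0.25 with an estimated correlation). Of 27 nuclear receptors known to bind these corepressors, Nr4a1, Ppara and Ppard rose, 4 when adjusted over the list alone, the latter pair 1.34-fold and 1.24-fold (list adjusted p = 0.0177, and adjusted p = 0.328 with an estimated correlation). Ppara lost its call without WT 1, WT 2, NS-DADm 1 or NS-DADm 2 (adjusted p up to 0.103), Ppard without any 1 sample (up to 0.197), with the atrial covariate (0.108) or with limma on either log scale of FPKM (up to 0.089), and the list without WT 1 (0.0681). Among 19 thyroid hormone response genes, 3 rose and 3 fell, 7 and 3 when adjusted over the list alone, and the list was not called (adjusted p = 0.83). PPAR target genes, with Ucp2 up 1.91-fold (not called without WT 1, WT 2, NS-DADm 1 or NS-DADm 3, adjusted p up to 0.119, or with limma, up to 0.0689), were not called (adjusted p = 0.426), and neither were other histone deacetylases (adjusted p = 0.934), where Hdac9, named after its values were seen, fell (log2 fold change -0.51, SE 0.09), or the circadian clock (adjusted p = 0.426), where Nfil3 rose 2.41-fold and Clock 1.26-fold. Clock lost its call without any 1 sample (adjusted p up to 0.125) and with limma (up to 0.12).

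Further lists were called higher with few members called. Glucocorticoid response genes had 4 rises of 20, 7 with 1 fall when adjusted over the list alone, with Cdkn1a up 2.49-fold and the metallothioneins Mt2 and Mt1 up 2.43-fold and 1.51-fold (Mt1 not called without WT 1 or WT 2, Mt2 without WT 2, adjusted p up to 0.0752 and 0.0501). FOXO target genes had 2 of 21 called, 7 when adjusted over the list alone, with Cdkn1a and the mitophagy receptor Bnip3 up, the latter 1.51-fold. Antioxidant genes had 3 of 27, 5 when adjusted over the list alone, with Nqo1, a quinone reductase, up 1.97-fold, Gpx1 1.45-fold and Hmox1 1.44-fold (Gpx1 not called without WT 2 or NS-DADm 1, adjusted p up to 0.0706, Hmox1 without any 1 sample, up to 0.129, with the atrial covariate, 0.0805, or with limma, up to 0.0544). Targets of LXR had 2 of 13, Pltp and Ucp2, with 5 when adjusted over the list alone. Extracellular matrix genes had 2 of 37, Ctgf and Tgfb3, with 4 when adjusted over the list alone. Lipid storage genes had 1 of 31, Plin3, with 2 when adjusted over the list alone, hypoxia genes 1 of 20, Bnip3, likewise when adjusted over the list alone, and endoplasmic reticulum chaperones and ribosomal proteins 0 of 20 and 0 of 76, also when adjusted over the list alone. The adjusted p with camera ran from 3.53e-06 for glucocorticoid response genes to 0.0252 for ribosomal proteins, and the adjusted p with an estimated correlation from 0.25 for hypoxia genes to 0.835 for ribosomal proteins. Hypoxia genes were also called by fry (adjusted p = 0.0174). Ribosomal proteins lost the call without WT 3 or NS-DADm 1 (adjusted p = 0.839 and 0.957), and lipid storage genes without NS-DADm 3 (0.166). Without WT 1 or WT 2 each of Tgfb3, Pltp and Plin3 lost its call, and so did Tgfb3 without NS-DADm 1 or 3, Pltp without WT 3, NS-DADm 1 or NS-DADm 2, and Plin3 without NS-DADm 2 or 3 (adjusted p up to 0.145, 0.127 and 0.0968). Tgfb3 was also not called with limma on either log scale of FPKM (up to 0.0798).

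Lists of energy metabolism and contraction had median log2 fold changes near 0, at 0.04 for sarcomere genes and -0.07 for calcium handling, while single sarcomere genes rose or fell. Nuclear-encoded oxidative phosphorylation (78 genes) and fatty acid oxidation (27 genes) had 0 called genes, also when adjusted over the list alone, with median log2 fold changes of -0.02 each (adjusted p = 0.0993 and 0.34). Tricarboxylic acid cycle genes had 0 of 19 called and a median of -0.06 (adjusted p = 0.0321, and adjusted p = 0.735 with an estimated correlation), and the call ended without WT 1, WT 2, NS-DADm 1 or NS-DADm 3 (adjusted p = 0.0996, 0.133, 0.205 and 0.166). Among 31 sarcomere genes, Myot, Mypn and Lmod2 rose, and Tpm1, Mybpc3 and Myom2 fell, with 6 in each direction when adjusted over the list alone (list adjusted p = 0.395). Tpm1 fell from 9423 ± 167 to 6622 ± 423 FPKM. Calcium handling had 3 falls of 24, 4 with 1 rise when adjusted over the list alone, with the calcium-binding protein Hrc down 1.41-fold (list adjusted p = 0.0655). Mybpc3 lost its call without any 1 sample (adjusted p up to 0.159) and with the atrial covariate (0.0591), and Mypn without WT 1 or WT 2 (up to 0.0533).

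**Figure D2:**
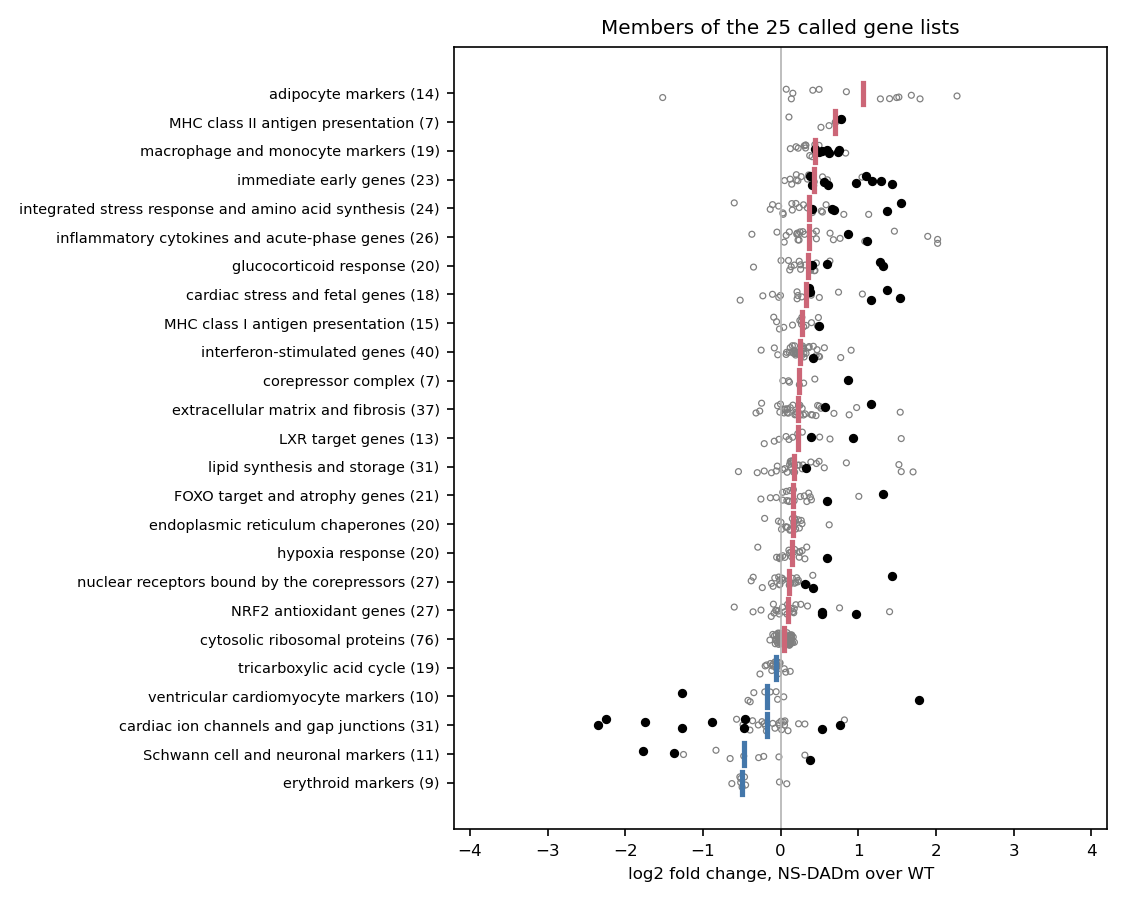
Log2 fold change, NS-DADm over WT, of every tested member of the 25 lists called with the preset correlation, with the number of tested members in parentheses. Filled points are called genes, open points are not, and the bar is the median, red above 0 and blue below.

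In all, 25 of 48 lists were called with the preset correlation, 20 higher and 5 lower. With an estimated correlation camera called 0 lists, with 6 at an unadjusted p under 0.05, and fry called 4. Those 4, of macrophage markers, ion channels, the corepressor complex and hypoxia, had estimated correlations of -0.004, 0.009, -0.012 and -0.038. None exceeds the preset 0.01, so a correlation above the preset does not account for the camera calls that these lists lost. Other divisions of the 6 samples into groups of 3 called 6 to 23 lists with the preset correlation. Those divisions still held part of the difference between NS-DADm and WT.

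Markers of other cell types moved in part. Erythroid markers had a median log2 fold change of -0.5, and 8 of 9 were negative, with Hba-a1 at 2739 ± 270 and 1862 ± 622 FPKM (list adjusted p = 0.0047, and adjusted p = 0.498 with an estimated correlation). Neuronal and Schwann cell markers were lower (adjusted p = 0.0102, and adjusted p = 0.498 with an estimated correlation), with Dbh, an enzyme of noradrenaline synthesis, down (log2 fold change -1.77, SE 0.41), and Pmp22 up. That call ended with no low-count filter (adjusted p = 0.174), with a mean FPKM of at least 1 (0.786) and without NS-DADm 2 (0.0586), while Dbh lost its own without any 1 sample (up to 0.174) and after thinning to equal depth (0.0847), and Pmp22 without WT 1, WT 2, NS-DADm 1 or NS-DADm 2 (up to 0.12). Ventricular markers were called lower (adjusted p = 0.0363, and adjusted p = 0.385 with an estimated correlation), with Kcnip2 down, Lrrc52 up and the abundant Myl2 at 19150 ± 2481 and 17990 ± 2393 FPKM. That call ended without WT 1, WT 2 or NS-DADm 1 (adjusted p = 0.109, 0.102 and 0.0515). Adipocyte markers were higher (median 1.06, adjusted p = 0.0177, and adjusted p = 0.639 with an estimated correlation), but without NS-DADm 3, where Adipoq reached 25.4 FPKM and the brown fat gene Ucp1 23.6, the median was -0.02 (adjusted p = 0.535), and the call also ended without WT 2 (0.255). Endothelial, smooth muscle and cardiomyocyte markers were not called (adjusted p = 0.717, 0.814 and 0.825), nor were fibroblast markers (0.202). Mesothelial and epicardial markers had a median log2 fold change of 1.64, with 6 of 7 positive, and as a list they did not pass (adjusted p = 0.0689). Nor did skeletal muscle markers (adjusted p = 0.148), of which Acta1 and Tpm2 rose of 8 tested, platelet markers (median 0.48, adjusted p = 0.34) or brown adipocyte markers (median 0.19, adjusted p = 0.42).

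Atrial transcripts differed between samples of the same group. The mean log2 CPM of Sln, Myl7 and Myl4 was 4.55, 2.29 and 8.43 in WT 1, 2 and 3 and 8.01, 5.22 and 8.71 in NS-DADm 1, 2 and 3. The list of atrial markers had a median log2 fold change of 0.66 and was not called (adjusted p = 0.0846). With this score as a covariate, 389 genes were called, of which 301 were among the 420, and all 420 kept their direction. The macrophage list kept a median of 0.42, whereas the adipocyte, ventricular, tricarboxylic acid cycle and nuclear receptor lists were not called. Within the samples of low score (WT 1, WT 2 and NS-DADm 2), edgeR called 979 genes, with 2463 at an unadjusted p under 0.05, and DESeq2 called 158. Within those of high score (WT 3, NS-DADm 1 and NS-DADm 3), edgeR called 0 genes, with 1119 at an unadjusted p under 0.05, and DESeq2 called 55.

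**Figure D3:**
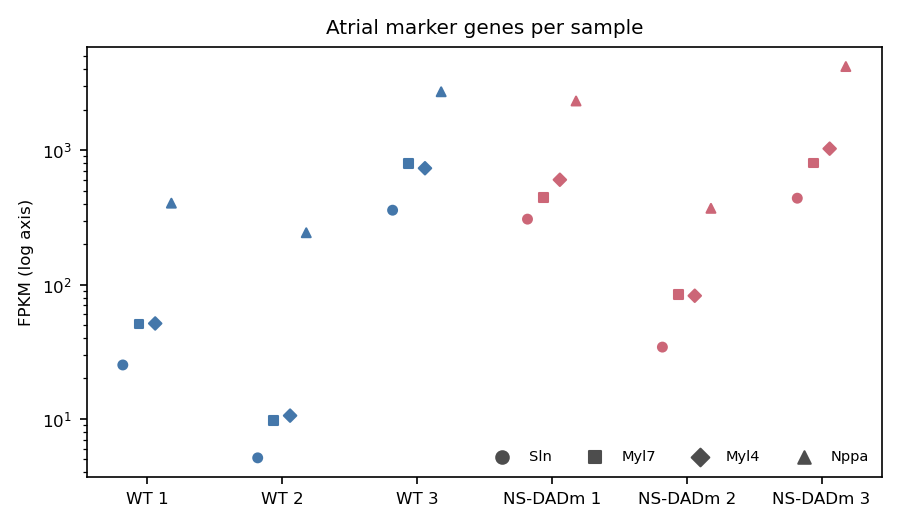
FPKM (log axis) of the atrial genes Sln, Myl7, Myl4 and Nppa in each of the 6 samples, WT in blue and NS-DADm in red. WT 3, NS-DADm 1 and NS-DADm 3 lie above WT 1, WT 2 and NS-DADm 2 in all 4 genes.

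At the level of transcripts, the most changed was a transcript of Nnt, which encodes the mitochondrial proton-translocating transhydrogenase. The longer of its transcript models, of 5355 bases, had 0.09, 0.07 and 0.03 FPKM in the WT samples, from 5, 4 and 2 counts, and 118 ± 7.2 FPKM in the NS-DADm samples. The ratio was 1860 (95% interval 1040 to 3720, counting error only). The shorter model, of 3666 bases, rose from 194.2 ± 6.0 to 338.6 ± 25 FPKM, and the gene as a whole rose 2.68-fold. In all, 17 of 17498 transcripts of 16 genes were called, 9 higher and 8 lower, and all 16 genes were also called at gene level. They included transcripts of Pttg1, Cyfip2, Ndrg4, Wdfy1, Tbl1xr1, Myot and Hcn2. The number of transcripts changed was 4, 3 and 4 without WT 1, 2 and 3, and 3, 7 and 3 without NS-DADm 1, 2 and 3. Nnt was chosen after its values were seen.

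**Figure D4:**
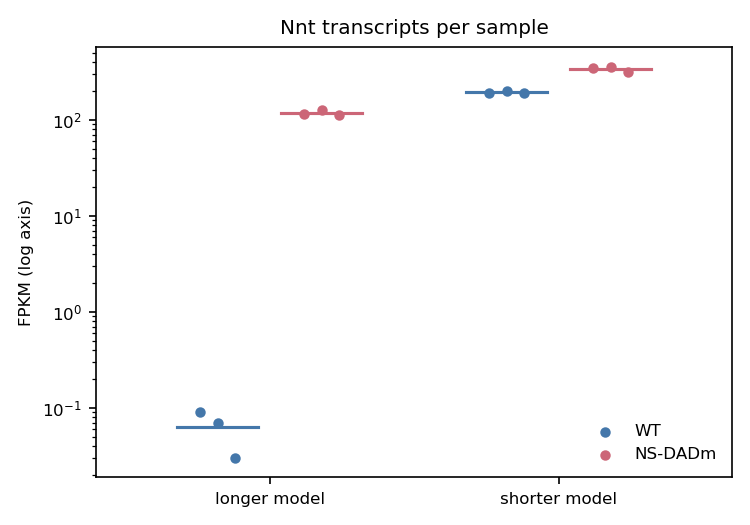
FPKM (log axis) of the longer and the shorter Nnt transcript model per sample, with group means as bars, WT in blue and NS-DADm in red. The longer model is at 0.09 FPKM or less in all 3 WT samples and at 112.87 FPKM or more in all 3 NS-DADm samples.

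Called genes were compared by their place in gene order, a comparison made after the data were seen. On the chromosome that holds Ncor1, 51 of 1096 tested genes were called (4.7%), against 3.1% of the others (Fisher's exact p = 0.0069), and of the 20 genes with the smallest p, 6 lay on it: Pttg1, Cyfip2, Ccng1, Olfr1372-ps1, Chd3 and Efnb3. Among the 150 tested genes on either side of Ncor1, 18 of 300 were called, 1.91 times the share of the other genes (Fisher's exact p = 0.011), and 4.1% of all windows of that size along the chromosomes, those around Ncor1 included, were at least as dense. With the same exact test, the ratio was 1.25 (p = 0.56) with 50 genes on either side, 2.06 (p = 0.014) with 100, 2.27 (p = 0.00012) with 200 and 1.94 (p = 0.001) with 250. That test takes neighbouring genes as independent, and 38.5%, 4.0%, 3.0% and 4.2% of all windows of these sizes were at least as dense. Pttg1 and Cyfip2, at -188 and -174 in the order of tested genes counted from Ncor1, lay outside the window of 150. The X chromosome had 27 of 431 called (6.3%, exact p = 0.0011), 8 higher and 19 lower.

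**Figure D5:**
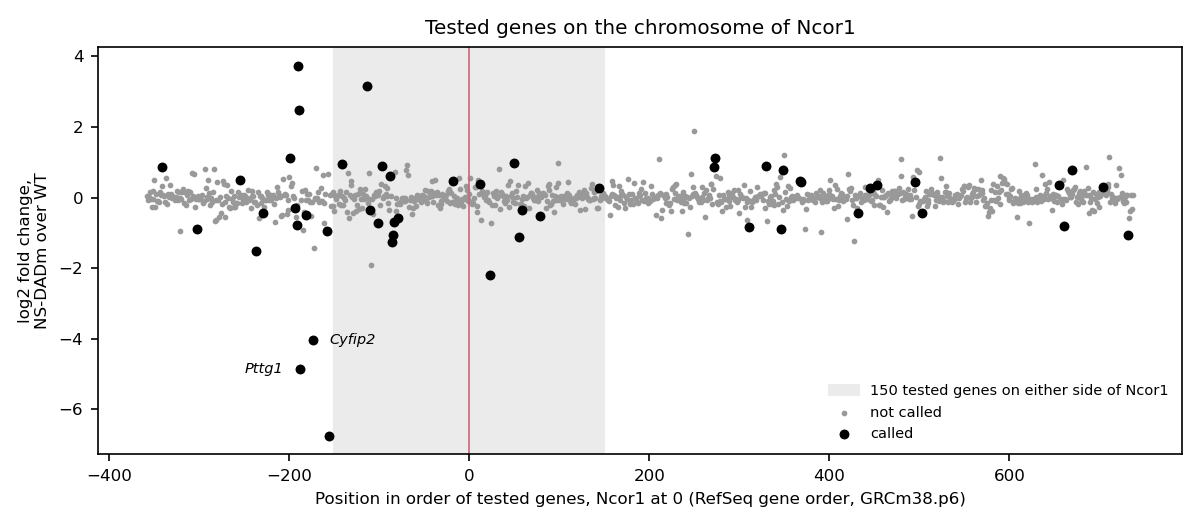
Log2 fold change, NS-DADm over WT, of the tested genes on the chromosome of Ncor1 in the gene order of GRCm38.p6, with Ncor1 at 0 and 150 tested genes on either side shaded. Black points are called genes, and Pttg1 and Cyfip2 lie outside the shaded window.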

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

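The atrial score, the thinning of libraries, the fits within libraries of like atrial score, the removal of genes near Ncor1 and the window widths were chosen after seeing the data. The number of genes changed (420) was 432 with DESeq2 size factors, 538 with no low-count filter and 402 with a mean FPKM of at least 1. It was 539 with DESeq2's test, 389 with the atrial score and 401 after thinning to equal depth. It was 262 with limma on log2(FPKM + 1) and 256 on log2(FPKM + 0.1), for reasons that were not tested. By construction it was 101 with a log2 fold change of at least 1 and 820 at an adjusted p under 0.10. Removal of the 300 tested genes nearest to Ncor1 left 402, also by construction. The 18 calls in that window were dropped with no new fit. Leaving out single samples gave 117 to 382 genes, 22 to 33 lists and 3 to 7 transcripts, where the smaller number of samples is part of the cause. Samples of low atrial score gave 979 genes with edgeR, 2463 at an unadjusted p under 0.05 and 158 with DESeq2, and those of high score gave 0, 1119 and 55, with 3 samples each and a lone sample of 1 group assumed to vary like the others. The cause of that difference was not tested. The lists called were 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 4 by fry, of 25. Of the called genes followed by name, all 77 kept their call with DESeq2 size factors, 63 with the atrial score and 33 without WT 2, and in none did the direction reverse in any setting.

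With a replicate block, the replicate number as a factor, the number of genes changed was 895, with 2 transcripts and 30 lists, all 25 among them. In a pairing check, the deviations of samples of the same number correlated at -0.05, 0.33 and 0.4 across genes. WT 2 and WT 3 were closest to the samples of their own number, but WT 1 was closest to NS-DADm 2 (0.19). In both matching pairs the samples also fell on the same side of the atrial score. WT 3 and NS-DADm 3 were alike, at 8.43 and 8.71, whereas WT 2 and NS-DADm 2 only shared the low side, at 2.29 and 5.22. The check therefore does not settle whether the numbers pair the samples.

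Leaving out single samples moved the log2 fold change of Ncor1 from 0.07 to 0.14 and of Hdac3 from -0.02 to 0.08. The median of the ribosome list ranged from 0 to 0.08. Signs changed only among values that had not passed or lost their call. In the same fits Cnp ranged from -0.14 to 0.1, Fabp4 from 0 to 0.11, Cfd from -0.04 to 5.25, Myl2 from -0.16 to 0.05, Myl3 from -0.05 to 0.1 and Pln from -0.12 to 0.01. After thinning Cnp was at 0.01, and with the atrial score Myl2 was at 0.08 and Pln at 0.07, and the cause was not tested.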

Other observations

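The tests of position near Ncor1, of Nnt, of residual blood and of Gene Ontology terms were chosen only after the results were seen, and the splits of the samples, the test of a common macrophage factor and the atrial test on macrophage markers were written before their results. Among the Gene Ontology terms of the deposited tables, of 45 tested genes of the term stress fiber, 36 had a positive log2 fold change and 4 rose, Acta1, Pdlim4, Sept9 and Amot, while Tpm1 fell and the others did not pass. The term was called higher by camera with the preset correlation (adjusted p = 0.00322), and not with an estimated correlation (adjusted p = 0.902) or by fry (adjusted p = 0.0765). Of 87 immune response genes, 62 had a positive log2 fold change and 8 rose, among them the protease Ctss and the inhibitory Fc receptor Fcgr2b, while Il15 fell, and this term too was called only with the preset correlation (adjusted p = 0.00153, against 0.902 with an estimated correlation and 0.125 by fry). Extracellular matrix (adjusted p = 0.013) and cellular response to mechanical stimulus (adjusted p = 0.0466) were likewise called higher with the preset correlation and not with an estimated one (adjusted p = 0.902 for each). In all, 18 of 1217 terms were called, all higher, and camera with an estimated correlation called 0 (adjusted p = 0.902 for each of the 18), with 53 at an unadjusted p under 0.05, and fry called 1.

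The 6 samples can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The real division called 420 genes, 17 transcripts and 25 lists, and in each case it was the only 1 of the 10 with as many. The highest of the other divisions called 70 genes, 1 transcript and 23 lists. Each of the others also called lists, 6 at the fewest, although all except that with 70 genes called 0 genes. List calls with the preset correlation thus arose under every division of the samples. Each other division mixed WT and NS-DADm unequally on its sides, so part of the difference between them stayed in it. List calls there therefore do not show how many would arise with no difference at all. The division with 70 genes and 23 lists set WT 1, WT 2 and NS-DADm 2 against the rest, which are the samples of low and of high atrial score.

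Called genes were denser near Ncor1 with 100 or more tested genes on either side. If the knock-in was made in stem cells of another strain, DNA of that strain could have been kept beside the gene through breeding and have changed the expression of neighbouring genes. The ratio of called shares was 1.91 with 150 tested genes on either side of Ncor1, and over 5 widths its lowest was 1.25, at 50 on either side, where the exact p was 0.56. Near Ncor1, strain DNA and a response to the mutated corepressors that does not depend on position cannot be told apart, because the widths gave different answers and the strain of the stem cells is not given in the sources used here.

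The longer Nnt transcript was nearly absent from the WT samples. C57BL/6J mice are known to carry a deletion in Nnt that other C57BL/6 lines lack, and the labels give only C57BL/6 for both groups. The lowest NS-DADm value was 1250 times the highest WT value, which is consistent with different substrains behind the groups. Reads of an unchanged gene divided differently between transcript models would have left the gene level as it was, but it rose 2.68-fold, and higher transcription of the same gene would have moved both models alike, but their fold changes differed 1010-fold. If the substrains differed, wholly or in part, other called genes might reflect substrain and not the knock-in. Such a difference would lie between the same groups as the knock-in, so this design does not separate substrain from knock-in.

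All 19 macrophage markers had a positive log2 fold change, of which 7 passed. More macrophages and nothing else would raise the markers by a common factor only if no other cells expressed them. Their log2 fold changes, from 0.12 to 0.84, differed by more than their errors (n = 19 markers, chi-square p of Cochran's Q = 0.00557). Expression of the markers in other cells was not measured, so the test does not decide whether a larger number of macrophages alone accounts for them. That test takes the markers as independent, and its errors rest on 3 samples per group. More residual blood would raise erythroid markers, whose median was -0.5. With the atrial score in the model the median of the macrophage markers was 0.42, against 0.44 without it, which argues against unequal atrial tissue as the cause. A change in macrophage number, a change of macrophage state, both together, and a response to the knock-in stay open.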
